A study of Mus musculus with 6 samples.

How the data were processed

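RNA was sequenced from lineage-negative, Sca-1-positive bone marrow cells of C57BL6/SJL mice 12 weeks after transplantation of stem cells with endogenous or overexpressed miR-125a, per the labels. The labels name 6 libraries, 3 per group. The deposited count table holds 4 of them, whose column headers match the sample numbers in the labels as endogenous replicates 1 and 3 and overexpressed replicates 2 and 3. The design fixed before the data were examined had 3 against 3, so every fit was made with 2 against 2 instead, and the remaining 2 libraries were not used here. Nothing in the labels names a batch, a sequencing date or the recipient of a library.

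The submitters' processing notes name FastQC 0.11.8, STAR and edgeR 3.24.3 and the mm10 build. The authors deposited whole-number counts per gene with no normalization. The STAR version, the counter, its annotation and its use of strand are not given in the sources used here, so reads of overlapping genes on opposite strands, of paralogs and of pseudogenes cannot be assigned with certainty. All 55450 gene identifiers matched the GENCODE vM21 annotation in identity and order, which gave symbols, positions, exon lengths and 3' UTRs. The authors also deposited a table of log2 fold changes and mean log2 CPM from edgeR, per the file headers. That deposited table gives a likelihood ratio and a signed score, the -log10 of the p-value with the sign of the fold, per the file headers and its values. Unadjusted p-values and FDR values were deposited by the authors as edgeR gave them, per the file headers. The sign of the deposited folds is not stated and was read from the counts.

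Counts were analysed with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM factors, quasi-likelihood fits with the dispersions of earlier edgeR versions, and the quasi-likelihood F test, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Folds are overexpressed over endogenous, and SE is the absolute log2 fold over the square root of F. Total counts ran from 654126 to 737431 per library. On genes simulated from the means and spread of these libraries, with 50 genes changed at each size among 10808, the F test found 0%, 0%, 10% and 62% of log2 folds of 1, 2, 4 and 6 and called 3 unchanged genes. A likelihood ratio test on the same fit found 2%, 8%, 90% and 96% with 42 unchanged genes called, and DESeq2 1.42.0 found 8%, 18%, 96% and 98% with 74. These simulations used shrunken dispersions and understate the spread of real genes. They changed only genes with larger mean counts, so the shares found need not hold for genes with few counts.

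Lists of genes for cell types, the cell cycle, responses and metabolism, 24 in all, were fixed before the data were examined. The 20 lists with at least 5 tested members, the sex-linked genes left out, were tested with camera (limma 3.58.1) on the edgeR fit with a preset correlation, and again with an estimated correlation and with fry. Adjusted p of lists is over these 20. Members were also adjusted over their list alone, each list separately, with no correction for the number of lists. In 20 tables simulated without change, 41 of 400 list tests by camera with the preset correlation had a p under 0.05 (10.2%). Of these tests 6 had an adjusted p under 0.05, in 6 of the 20 tables. The erythroid list made 2 of these 6 calls. With the estimated correlation 1 test had a p and 0 an adjusted p under 0.05, and with fry 22 and 0. Genes were drawn independently in these tables, so correlation between the genes of a list was not simulated. The lists overlap in a few genes, such as Mcl1, Bak1 and Flt3.

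The genes named were set by a rule made before the data were examined: called genes by size of change, called members of each list, and, where nothing was called, the 5 genes with the smallest p in each direction and the 2 members of each list with the smallest p. Other list members, Klf13, Ly6d and H2-Aa among them, were chosen after their values were seen. For genes at 0 in a whole group, the fold was taken against 3 counts over that group, and for 1 to 3 counts the ratio of summed counts has an exact interval, all scaled by effective library size.

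Seed sites complementary to the start of miR-125a-5p (CTCAGGG) were searched in the longest annotated 3' UTR of each tested gene. The median log2 fold of genes with a site minus that of genes without was ranked among all 420 rearrangements of the same bases. Simulated shifts of -0.5 and -0.2 were found in 20 and 12 of 20 tables, and a shift of 0 in 0 of 20. The simulated folds were drawn independently for each gene from 1 normal distribution.

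Background was measured from the 1479 odorant, vomeronasal and trace-amine receptor genes (5478.3 kb of exon) with 1000 bootstrap resamples over genes. A gene was taken as above background where its mean density exceeded 8.27 counts per kb, the value that 95% of receptor genes do not exceed. This measure was chosen after the data were seen.

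The test behind the deposited table was found by trying several dispersion and test recipes with different library sizes and comparing their likelihood ratios with the deposited ones. The lowest of the authors' tested genes had a second-highest CPM of 8.14 and the highest gene left out 7.64, so a threshold of 8 CPM in at least 2 libraries was used for that filter. The alternatives fixed beforehand were other scalings, filters, dispersions and tools, removal of mitochondrial, haemoglobin and immunoglobulin genes, and removal of each library in turn. For each removal of a library the count filter was rerun, so the tested genes and list members changed as well. Tests with a likelihood ratio, the deposited filter and genes above background were added after the data were seen.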

Results

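MicroRNA-125a (miR-125a) was overexpressed in mouse haematopoietic stem cells, which were transplanted into irradiated recipients, and RNA was sequenced from sorted bone marrow cells 12 weeks later. Each library was made from 2000 lineage-negative, Sca-1-positive cells, a fraction that holds stem cells and early progenitors, with a low-input kit that amplifies full-length cDNA. The labels name 3 libraries with endogenous miR-125a (replicates 1, 2 and 3) and 3 with overexpressed miR-125a (replicates 1, 2 and 3). The counts analysed here cover 4 of these 6, endogenous replicates 1 and 3 and overexpressed replicates 2 and 3, so each group has n = 2. The other 2 were not analysed here. Total counts of the 4 analysed libraries were 654126 and 712311 for endogenous replicates 1 and 3, and 737431 and 715930 for overexpressed replicates 2 and 3. The labels do not say whether the libraries of a group came from separate recipients, so the p-values below measure only the spread between these libraries, which may be technical.

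The libraries held a few abundant rows and a broad low-level signal. The 10 rows with the most counts, among them Brd7, Gm10800, Klf13, Gm37720, Irf2bpl, Gapvd1, Parp14 and the neutrophil granule gene Ltf, took 12.8% and 12.4% of the counts in endogenous replicates 1 and 3, and 14.98% and 15.78% in overexpressed replicates 2 and 3. Mitochondrially encoded genes took 4.14%, 4.22% and 6.29% in endogenous 1, endogenous 3 and overexpressed 2, but 0.558% in overexpressed 3. Ribosomal protein genes took 0.331%, 0.481%, 0.483% and 0.167% in the same order. Odorant, pheromone and trace-amine receptor genes, whose products serve smell and pheromone sensing, held 2.87, 3.77, 2.56 and 3.42 counts per kb of exon, against 4.98, 5.43, 5.62 and 5.45 for all genes. Of the 1479 receptor genes, between 87.8% and 91.8% had at least 1 count in a library. Receptor genes with a single exon block held 1.91, 2.57, 1.503 and 2.08 counts per kb and the others 2.92, 3.84, 2.62 and 3.50, so the signal was not even. If it were spread evenly over all exons, the mean receptor density would equal 57.6% of the counts in endogenous 1 (95% bootstrap interval over receptor genes 49.2 to 67.8), 69.5% in endogenous 3 (63.5 to 76.6), 45.6% in overexpressed 2 (39.8 to 52.4) and 62.8% in overexpressed 3 (52.9 to 74.6). At the median receptor density these shares were 29.5%, 48.8%, 26.4% and 32.2%. Across the 5323 genes with a mean count of 20 or more, which are not independent replicates, log2 CPM correlated at r = 0.443 between the endogenous libraries and r = 0.531 between the overexpressed libraries, and most closely between endogenous 1 and overexpressed 3 (r = 0.617).

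**Figure D1:**
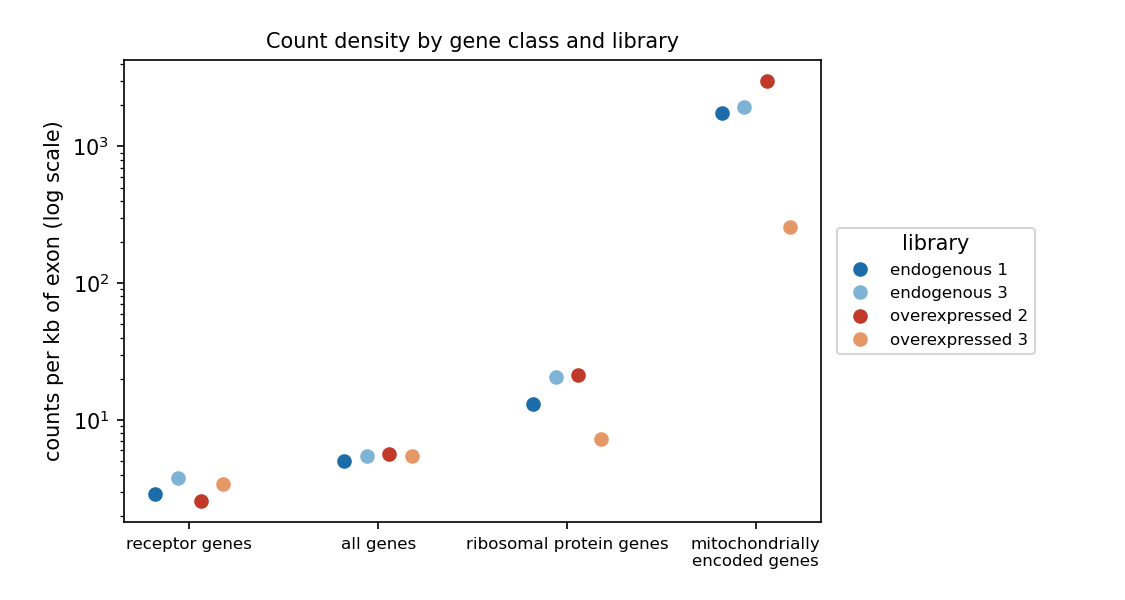
Counts per kb of exon (log scale) for odorant, pheromone and trace-amine receptor genes, all genes, ribosomal protein genes and mitochondrially encoded genes, 1 point per library. Receptor genes lie between 2.56 and 3.77 counts per kb in the 4 libraries, and overexpressed replicate 3 has the lowest mitochondrial density, 258.6 counts per kb.

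The overexpressed locus was examined first. Mir125a, on chromosome 17 at 17830812 to 17830879 of the mm10 build, had 0, 0, 0 and 1 counts in endogenous 1, endogenous 3, overexpressed 2 and overexpressed 3. Its host gene Spaca6 (chromosome 17, 17827158 to 17843009) had 1, 1, 2 and 2 counts, and the neighbouring microRNA genes Mir99b and Mirlet7e had 0 counts in each library. These rows lay below the count filter. The kit does not capture mature microRNA, and a vector transcript need not map to these rows, so the counts neither show nor exclude the overexpression that the labels state.

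The main comparison asked which transcripts differed in marrow progenitors when miR-125a was overexpressed. The genes with the smallest p-values that were lower with overexpression were Iglc3, an immunoglobulin light-chain constant gene (57 and 54 counts against 1 and 1), Cops9, a COP9 signalosome subunit (27 and 39 against 2 and 2), Hint1 (23 and 46 against 0 and 1), the actin-severing factor Cfl1 (263 and 323 against 1 and 4) and the proteasome activator Psme3 (64 and 48 against 4 and 4). Those that were higher were Elob, an elongin subunit (1 and 2 against 30 and 28), Tchh, a structural protein of the hair follicle (0 and 0 against 54 and 39), the transcript 5031434C07Rik (2 and 2 against 24 and 22), the secretory vesicle GTPase Rab3d (9 and 8 against 180 and 237) and the processed pseudogene CT025622.1 (1 and 2 against 14 and 27). At the planned count filter none of these passed the test: by edgeR's quasi-likelihood F test, 0 of 10808 genes had a Benjamini-Hochberg adjusted p under 0.05, while 566 had an unadjusted p under 0.05, where chance gives 540. With no low-count filter, the same test called 327 of 46089 genes higher and 495 lower, these 10 among them. On the 10808 genes DESeq2 called 151, 57 higher and 94 lower, and limma-voom with quality weights called 0, with 263 at an unadjusted p under 0.05. In libraries simulated with shrunken dispersions, which understate the spread of these, only genes with larger mean counts were changed. There the quasi-likelihood test found 0% of genes changed by a log2 fold of 2, 10% of those changed by 4 and 62% of those changed by 6, so at that filter only very large changes could be called.

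The fitted log2 folds of these genes, which depend on a prior count where a group holds few counts, were -5.52 ± 0.62 (SE) for Iglc3, -3.83 ± 0.485 for Cops9, -5.65 ± 0.80 for Hint1, -6.70 ± 0.99 for Cfl1 and -3.67 ± 0.57 for Psme3. Those of the higher genes were 4.30 ± 0.52 for Elob, 3.58 ± 0.51 for 5031434C07Rik, 4.70 ± 0.77 for Rab3d and 3.78 ± 0.63 for CT025622.1, with adjusted p from 0.771 to 0.814 by the edgeR test. From the summed counts, scaled by effective library size, Tchh was at least 34-fold higher with overexpression, taking 3 counts over the endogenous group as its floor. The mean densities of Tchh and 5031434C07Rik were not above that of 95% of receptor genes. With intervals that cover counting error only, since the kit has no molecular identifiers, Iglc3 was 50.7-fold lower (95% exact interval 13.7 to 424), Hint1 63-fold lower (10.9 to 2520), Elob 21.2-fold higher (6.9 to 106) and CT025622.1 15-fold higher (4.78 to 75.6). Iglc3, Elob, Hint1 and Cfl1 have close paralogs or pseudogenes that can share reads with them. Elob lies on chromosome 17 at 23824738 to 23829136 and Tchh on chromosome 3 at 93442330 to 93449077. Rab3d lies on chromosome 9 at 21907491 to 21918192, Iglc3 on chromosome 16 at 19065230 to 19065681 and Cfl1 on chromosome 19 at 5490455 to 5495201.

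Cell cycle lists were lower with overexpression by camera at its preset correlation, but not with an estimated correlation or by fry. Of 15 tested mitosis genes, 10 had lower and 5 higher values, with a median log2 fold of -0.83. Of the 24 listed, 5 were above background, so most of the tested genes were not. Of those above background only Bub1b was higher (log2 fold 1.44). With the count filter rerun, the median was -1.72 over 17 members without overexpressed 2 and -0.35 over 19 without endogenous 1. The tested members thus changed along with the library. Cdk1, the mitotic kinase, had 327 and 27 counts in the endogenous libraries against 4 and 4 (log2 fold -5.43 ± 1.47, -2.33 without endogenous 1), and Ube2c, which feeds substrates to the proteasome at mitotic exit, had 157 and 35 against 5 and 3 (-4.50 ± 1.08, -2.69 without endogenous 1). The proliferation marker Mki67 went the other way, with 12 and 50 against 176 and 3 counts. Of 11 tested DNA replication genes, 9 had lower and 2 higher values, with a median of -0.70. Here too the members changed with the library: the median was -1.18 over 14 without endogenous 1 and -0.07 over 12 without endogenous 3. Of the 22 listed, 6 were above background. Among the tested ones of these, Mcm4 was higher (log2 fold 2.64) and Pcna, Rrm1, Uhrf1 and Slbp were lower. The histone mRNA binding protein Slbp had 228 and 158 against 6 and 9 counts (-4.59 ± 0.80), and the ribonucleotide reductase subunit Rrm1 had 10 and 1504 against 4 and 9 (-6.59 ± 2.19, -0.67 without endogenous 3). At the preset correlation the camera adjusted p was 0.038 for mitosis and 0.045 for DNA replication. With an estimated correlation the unadjusted camera p from edgeR was 0.162 for mitosis and 0.128 for DNA replication, and both had an adjusted p of 0.978, and of 0.966 by fry. In 20 tables simulated without change the preset correlation gave 10.2% of lists a p under 0.05, and 6 tables had a list with an adjusted p under 0.05. Genes were drawn independently in those tables, while the estimated correlation was 0.095 for mitosis and 0.039 for DNA replication. These shares may thus understate the error for the real lists. No member passed over all genes tested. Adjusted over the list alone, with no correction for the number of lists, 1 DNA replication gene passed by the edgeR test, Slbp (adjusted p = 0.0137). By that adjustment 0 mitosis genes passed, of which 4 had an unadjusted p under 0.05. Without overexpressed replicate 3, the library with the low mitochondrial share, the adjusted p was 0.825 for mitosis and 0.167 for DNA replication, without endogenous 1 it was 0.29 for mitosis, and without endogenous 3 it was 0.0891 for DNA replication.

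The erythroid list was also lower by camera at the preset correlation, but not with an estimated correlation or by fry, and the direction of its median rested on 1 library. Of 8 tested members 7 had lower values and 1 a higher value, with a median log2 fold of -0.96. With the count filter rerun, the median was 0.72 over 8 members without endogenous 3. Without overexpressed 2 it was -5.25 over 11 members, so there the members changed along with the library. The camera adjusted p was 0.045 at the preset correlation. With an estimated correlation, 0.626 for this list, the unadjusted camera p was 0.35 and the adjusted p 0.978. By fry the adjusted p was 0.966. At the preset correlation this list was called in 2 tables simulated without change, in which genes were drawn independently. Tfrc, the transferrin receptor, which dividing cells of other lineages also use, had 299 and 655 counts against 44 and 36 (-3.38 ± 0.79) and passed when adjusted over the list alone (adjusted p = 0.0425), the only member to do so. Haemoglobin alpha, Hba-a1, whose duplicate copy can share its reads, had 9 and 182 counts against 12 and 0, and Car2 had 17 and 1021 against 9 and 111. Most haemoglobin counts came from endogenous replicate 3 and overexpressed replicate 2, and the adjusted p of the erythroid list was 0.797 without endogenous 3 and 0.289 without overexpressed 3.

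MHC class II genes, which mark antigen-presenting cells, had values in opposite directions. Among 14 tested dendritic cell markers, 4 passed when adjusted over the list alone and 0 over all genes. The adjustment over the list alone made no correction for the number of lists. Over all genes the adjusted p of these 4 by the edgeR test ran from 0.814 to 0.845. The MHC class II beta chains H2-Ab1 (179 and 53 counts against 3 and 3, log2 fold -5.18 ± 1.008, adjusted p = 0.0171 over the list alone) and H2-Eb1 (37 and 23 against 1 and 4, -3.44 ± 0.68, 0.0171) were lower. Ly6d was lower too (100 and 10 against 0 and 1, 0.0299), 100-fold by scaled summed counts with an exact interval of 17.7 to 4000. That interval covers counting error only and not the spread between libraries, and most Ly6d counts came from endogenous replicate 1. H2-Aa, the alpha chain that pairs with H2-Ab1, was higher (7 and 9 against 96 and 801, 5.85 ± 1.28, 0.018). These values are from the edgeR test. Ly6d and H2-Aa were added to the genes named here after their values were seen. The list as a whole had a median of 0.28, a mean of -0.57 and a camera direction of lower (adjusted p = 0.781). Of 9 B-lineage genes, 6 had lower and 3 higher values (median -0.80, camera adjusted p = 0.0783). Pou2af1, a B-cell transcriptional coactivator, had 23 and 78 against 4 and 3 counts (-3.61 ± 0.72) and was the 1 member that passed over the list alone (adjusted p = 0.0225). The B-cell surface marker Ms4a1 had 98 and 21 against 6 and 10 counts (-2.86 ± 0.94, adjusted p = 0.845 by the edgeR test). Its log2 fold ran from -3.65 to -1.0 without 1 library.

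**Figure D2:**
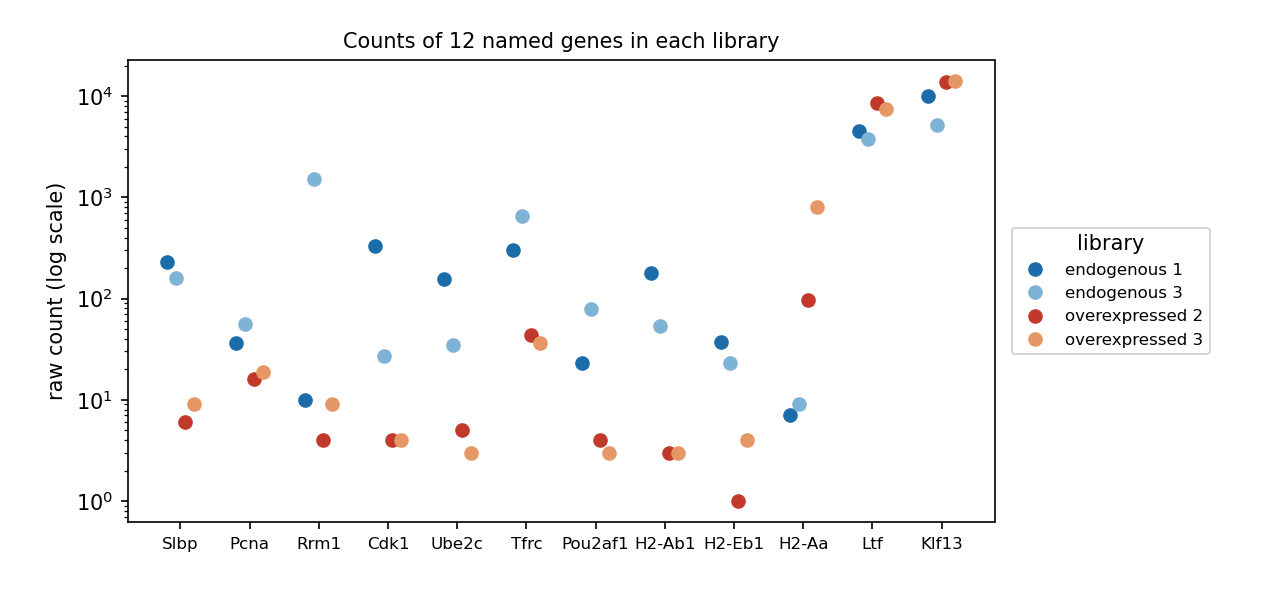
Raw counts (log scale) of 12 named genes, 1 point per library. Slbp, Tfrc, Pou2af1, H2-Ab1 and H2-Eb1 are lower in both overexpressed libraries than in both endogenous libraries, H2-Aa is higher, and Rrm1 owes its high endogenous value to 1504 counts in replicate 3.

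Reported direct targets of miR-125, which repression would lower, showed no common direction. Of 20 tested members, 12 had higher and 8 lower values, with a median log2 fold of 0.22, a mean of -0.01 and a camera direction of higher (adjusted p = 0.781). The anti-apoptotic gene Mcl1 had 11 and 166 counts against 12 and 6 (-3.003 ± 1.217, -0.31 without endogenous 3), and the Runx partner Cbfb had 12 and 12 against 26 and 19 (1.04 ± 0.44). Klf13, which was among the most abundant rows and was picked after its values were seen, had 9942 and 5146 against 13785 and 14079 counts (log2 fold 0.96, adjusted p = 0.894 by edgeR). By the edgeR test 0 targets passed over all genes or when adjusted over the list alone, 1 had an unadjusted p under 0.05, and 7 of the 35 listed targets had a count density above that of 95% of receptor genes. The pro-apoptotic target Bak1 had 4, 10, 5 and 4 counts, under the filter.

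Genes with a seed site for miR-125a-5p in the 3' UTR were not lower than genes without one. The 1533 genes with a 7mer or 8mer site had a median log2 fold of 0.049, and the others -0.013, a shift of 0.062. Of 420 rearrangements of the 7mer's bases, 340 gave a shift as low or lower (one-sided exact rank p = 0.81). The camera p for the set was 0.286 at the preset and 0.382 with the estimated correlation, in the direction of higher. In folds drawn independently from 1 normal distribution with the standard deviation of these, a shift of -0.5 was found in 20 of 20 tables and a shift of -0.2 in 12 of 20. Correlation between genes was not simulated, so these shares need not hold for the real folds. Counts that do not come from the gene's own transcripts would shrink any shift.

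Lists for other cell types had 0 members past the edgeR test over all genes or over the list alone, and 0 at an unadjusted p under 0.05. Of 30 stem cell genes 15 were tested, 8 higher and 7 lower in value (median 0.12, mean -0.02, camera direction higher, adjusted p = 0.889), and 3 had a density above that of 95% of receptor genes. Fgd5 had 116 and 100 against 363 and 99 counts (1.26 ± 0.90, from -0.08 to 1.97 without 1 library). Robo4 had 10 and 79 against 14 and 11 (-1.58 ± 0.88, from -2.24 to 0.28), while the stem cell surface marker Procr had 1 count in each library. Of 14 granulocyte-monocyte genes 12 were higher and 2 lower in value (median 0.46, adjusted p = 0.229), and the camera direction turned to lower without overexpressed 2. Ltf had 4538 and 3735 against 8490 and 7413 counts (1.06 ± 0.68, from 0.78 to 1.49 without 1 library) and Irf8 4 and 25 against 60 and 7 (1.47 ± 1.14, from -0.87 to 3.05). The neutrophil genes Ngp (45 and 364 against 1042 and 28) and Camp (14 and 241 against 617 and 11) did not follow Ltf. Lymphoid progenitor genes had a median of 0.35 over 6 members (adjusted p = 0.781), with Flt3 at 56 and 37 against 242 and 33 counts and Satb1 at 19 and 48 against 19 and 21. T, NK and innate lymphoid genes had a median of -0.10 and a mean of 0.38 over 5 members (camera direction higher, adjusted p = 0.889), with Nkg7 at 19 and 25 against 208 and 15 counts and Il1rl1 at 11 and 17 against 9 and 10. Endothelial and stromal genes had a median of 0.24 over 14 members (adjusted p = 0.781), with Col1a2 at 34 and 25 against 14 and 16 and Lepr at 10 and 7 against 9 and 21. Megakaryocyte genes (4 tested, median 0.41) and mast cell, basophil and eosinophil genes (3 tested, median 0.60) were too few for a list test. Itga2b had 14 and 22 against 28 and 16 counts and Treml1 117 and 54 against 160 and 89. Cyp11a1 had 22 and 27 against 19 and 75, and Epx 25 and 16 against 16 and 19.

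Response and housekeeping lists likewise had 0 members past either adjustment by the edgeR test, and at an unadjusted p under 0.05 they had 9 ribosomal protein genes, 2 respiratory chain genes, 1 glycolytic enzyme and 1 Bcl2 family gene. Interferon-stimulated genes had a median of -0.11 over 11 members (adjusted p = 0.889), with Ddx58 at 10 and 9 against 53 and 12 counts and Ly6e at 61 and 11 against 9 and 12. NF-kB-induced genes had a median of -0.77 over 7 (0.888), with Nfkbia at 198 and 20 against 14 and 18 and Cd83 at 28 and 10 against 84 and 30. Bcl2 family genes had a median of -0.59 over 5 (0.888), with Mcl1 as above and Bcl2l11 at 10 and 6 against 10 and 23. The 4 tested p53 targets, too few for a list test, had a median of -0.38, with Zmat3 at 15 and 13 against 6 and 10 and Mdm2 at 15 and 17 against 11 and 10. Immediate-early genes had a median of 0.20 over 5 (0.889), with Jun at 11 and 7 against 15 and 8 and Egr1 at 14 and 22 against 22 and 15. Cholesterol synthesis genes had a median of -0.22 over 8 (0.889), with Srebf2 at 21 and 10 against 31 and 30 and Cyp51 at 27 and 22 against 15 and 14. Glycolytic enzymes had a median of 0.67 and a mean of -0.09 over 5 (0.781, direction higher), with Eno1, which has pseudogenes, at 155 and 12 against 10 and 6 and Hk1 at 7 and 15 against 16 and 18. Respiratory chain genes had a median of 0.24, a mean of 0.07 and a camera direction of lower over 29 (0.889), with Ndufc1 at 11 and 26 against 1 and 1 and Cox6a1 at 20 and 43 against 6 and 0. Ribosomal protein genes, whose pseudogenes can share reads, had a median of 0.27, a mean of 0.11 and a camera direction of lower over 63 (0.949), with Rpl19 at 3 and 11 against 38 and 61 and Rpl3 at 178 and 210 against 5 and 19. The camera direction of the ribosomal list turned to higher without endogenous 3 or without overexpressed 3. Mitochondrially encoded genes had a median of -0.07, a mean of 0.08 and a camera direction of lower over 11 (0.888), with mt-Rnr1 at 521 and 1697 against 947 and 304 and mt-Tp at 15 and 26 against 30 and 14. Of the sex-linked genes, used only to check the libraries, Xist alone was tested (84 and 109 against 69 and 15 counts), and 4 Y-linked genes had 1 count in all 4 libraries together.

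**Figure D3:**
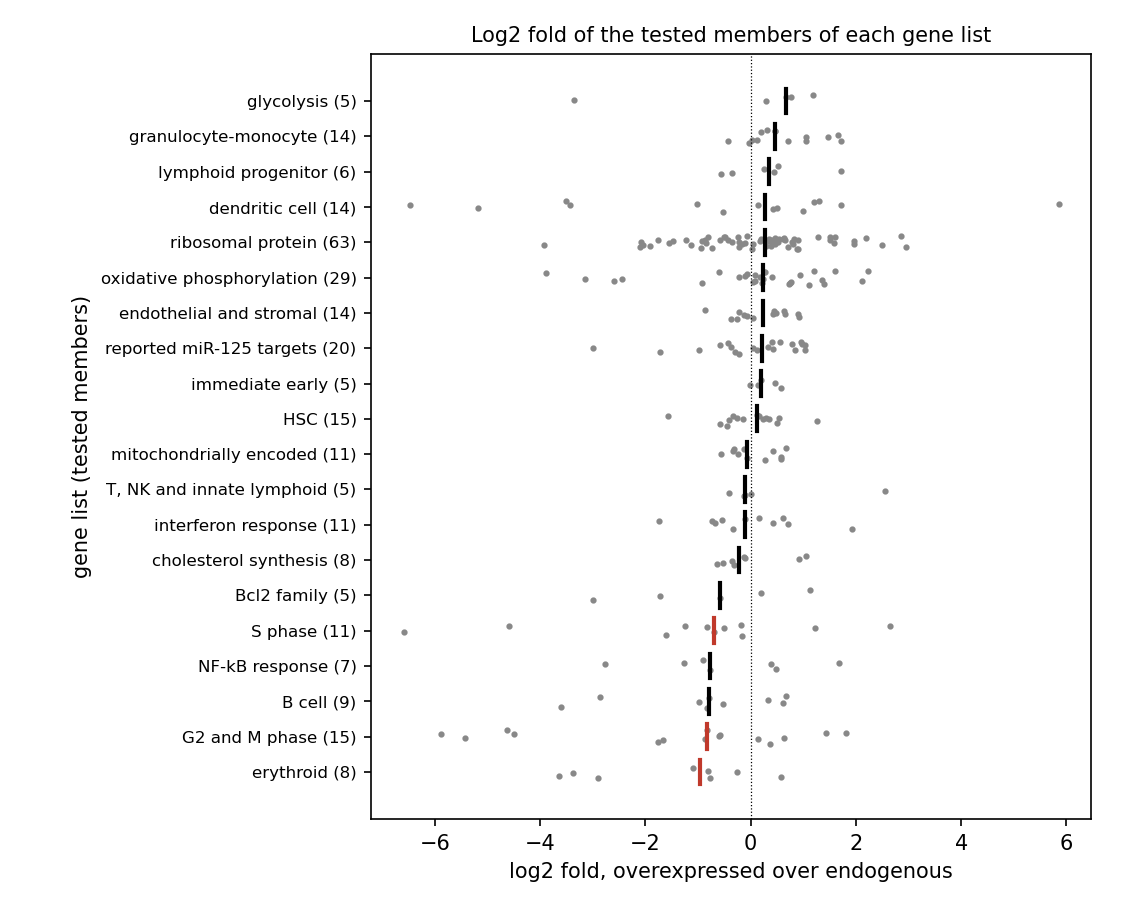
Log2 fold of overexpressed over endogenous libraries for each tested member (grey points, with vertical jitter) of the 20 tested lists, with the list median as a bar, red where the camera adjusted p at the preset correlation was under 0.05. The 3 red medians lie at -0.96 (erythroid), -0.83 (mitosis) and -0.70 (DNA replication), and each of these lists had an adjusted p of 0.978 with an estimated correlation and 0.966 by fry.

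The authors' deposited table of the same comparison listed more changes. It tested 17039 genes and held 404 with a false discovery rate under 0.05, of which 155 had a negative and 249 a positive log2 fold. Its sign was opposite to that used here, so that positive values were higher in the endogenous libraries. Of these 404, 232 passed the count filter used here. Prss34, Fos and Ier5 were among those that did not, with deposited log2 folds of -6.4, 5.64 and 6.97. For genes named above, the deposited values were -8.64 for Tchh, -4.32 for Elob, -4.71 for Rab3d, 5.51 for Iglc3, 6.69 for Cfl1, 4.58 for Slbp, 5.45 for Cdk1 and 5.19 for H2-Ab1 in the authors' deposited table, with false discovery rates between 2.74e-06 and 0.0122. Its likelihood ratios were recovered to within 4.9e-08 by a likelihood ratio test on the quasi-likelihood fit. The quasi-likelihood F test on the same 17039 genes called 0, with 891 at an unadjusted p under 0.05 and 852 by chance, while DESeq2 called 164 and a likelihood ratio test with gene-wise dispersions 65. Of the 404 deposited calls, 61.4% had over 80% of their summed CPM in a single library. So did 2% of all genes in that table, which were not selected for a large difference. The groups did not overlap in 63.9% of the calls and in 32.8% of all genes in that table. The calls were selected for a group difference in the same counts.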

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

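Chosen only after results were seen were the likelihood ratio tests, the filter of the deposited table and the restriction to genes above background; the other alternatives were fixed beforehand. The count of called genes depended on the test and the filter. The quasi-likelihood F test of edgeR called 0 genes under each scaling (566 at an unadjusted p under 0.05 with TMM, 564 with RLE, 568 with upper-quartile factors, 692 with no composition factors, where chance gives 540 for each). It also called 0 with at least 10 counts in every library of a group (838 of 9501, where chance gives 475), with newer (653) or robust (548) dispersions, without mitochondrial, haemoglobin and immunoglobulin genes (572), with the deposited filter (891 of 17039) and among the 2860 genes above background (149, where chance gives 143). Limma-voom also called 0, with 263 at an unadjusted p under 0.05. With no low-count filter 327 genes were called higher and 495 lower. DESeq2 called 57 higher and 94 lower, the likelihood ratio test on the quasi-likelihood fit 103 higher and 169 lower, the likelihood ratio test with gene-wise dispersions 26 higher and 58 lower, and the filter of the deposited table with the likelihood ratio test on the quasi-likelihood fit 155 higher and 249 lower. With no filter 46089 genes were tested. On the same 17039 genes and fit, the change from the F test to the likelihood ratio test took the calls from 0 to 404, so there the difference comes from the test statistic; for the other differences the cause was not tested. Without each library in turn, between 12934 genes (without endogenous 3) and 14610 genes (without endogenous 1) passed the rerun count filter. Such a fit leaves 1 library in a group, which is assumed to vary like the other group. The planned removal of the 2 libraries absent from the count table was not run. No paired analysis was possible because the groups share only replicate number 3, so the planned fits with a replicate block were not run.

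Of 58 named genes, 43 had 1 sign under every alternative that tested them, Slbp, Tfrc, Cdk1, H2-Ab1, Iglc3 and Elob among them. In each gene named here the groups did not overlap, so removal of 1 library could hardly turn the sign. For such genes the count of 43 is no test of robustness. With no composition factors the median of all genes moved to -0.29, and Egr1 (-0.12) and mt-Tp (-0.06) changed sign. Among genes that kept their sign, the log2 fold without 1 library ran from -7.46 to -0.67 for Rrm1, -6.35 to -2.33 for Cdk1, -5.28 to -2.69 for Ube2c, -3.77 to -0.31 for Mcl1, -3.65 to -1.0 for Ms4a1, 0.45 to 1.83 for Klf13 and 3.82 to 6.71 for H2-Aa. For those that turned it ran from -2.24 to 0.28 for Robo4, -0.08 to 1.97 for Fgd5, -0.47 to 2.57 for Flt3, -0.87 to 0.03 for Satb1, -0.46 to 3.49 for Nkg7, -0.87 to 3.05 for Irf8, -0.07 to 0.91 for Itga2b, -0.11 to 1.69 for Cyp11a1, -0.56 to 0.52 for Epx, -2.58 to 0.32 for Ly6e, -0.12 to 1.11 for Jun, -0.16 to 0.56 for Egr1, -3.67 to 0.07 for Nfkbia, -1.70 to 0.27 for mt-Rnr1 and -0.44 to 0.83 for mt-Tp. Among the named genes, DESeq2 called 14, the likelihood ratio test on the quasi-likelihood fit 27, that with gene-wise dispersions 22 and the fit with no filter 27.

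The lower erythroid, DNA replication (S phase) and mitosis (G2 and M phase) lists passed with RLE size factors (adjusted p 0.0388, 0.0388 and 0.0349) and did not with the estimated correlation (0.978 for each) or fry (0.966 for each); the cause was not tested. Without 1 library the adjusted p ran from 5.99e-07 to 0.797 for the erythroid list, 0.000116 to 0.167 for DNA replication and 0.000949 to 0.825 for mitosis. Over the same removals it ran from 0.000786 to 0.27 for B cell genes, 3.14e-05 to 0.766 for granulocyte-monocyte genes, 0.72 to 0.939 for miR-125 targets, 0.572 to 0.951 for stem cell genes, 0.323 to 0.827 for T, NK and innate lymphoid genes, 0.255 to 0.925 for dendritic cell genes, 0.684 to 0.916 for interferon genes, 0.000409 to 0.825 for immediate-early genes, 0.826 to 0.918 for cholesterol synthesis, 0.0192 to 0.913 for glycolysis, 2.23e-06 to 0.323 for respiratory chain genes and 2.43e-05 to 0.689 for mitochondrially encoded genes. The count filter was rerun for each removal, so the tested members also changed. The camera direction turned at least once in these lists, except in the B cell, erythroid, DNA replication and mitosis lists, and the erythroid median turned from -0.96 to 0.72 without endogenous 3. A kept direction was not particular to those lists. The lymphoid progenitor, endothelial and stromal, Bcl2 family and NF-kB lists, none of which passed in the main test, kept theirs too. Ribosomal protein genes ran from 6e-08 to 0.681, being lower without overexpressed 2 (6e-08) and higher without overexpressed 3 (1.77e-06).

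The seed-site shift stayed above 0 under each alternative, at 0.029 with 8mer sites, 0.055 with any site class, 0.07 with the shortest 3' UTR, 0.04 among genes above the median CPM, 0.161 among genes above background and 0.022 to 0.128 without 1 library.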

Other observations

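Of the tests in this part, those of receptor-gene background by reads shared between paralogs and by genomic DNA of female cells, and that of more background in the overexpressing libraries, were set before their results were seen; the remaining tests were chosen only afterwards. Several cell type and cell cycle genes had most of their counts in a single library. The neutrophil genes S100a8, Ngp and Camp had 36, 1130, 739 and 205 counts, 45, 364, 1042 and 28 counts, and 14, 241, 617 and 11 counts in endogenous 1, endogenous 3, overexpressed 2 and overexpressed 3. The spindle genes Nusap1 and Kif20b had 745 and 751 counts in endogenous 1 and at most 13 and 19 in any other library. Siglech, a plasmacytoid dendritic cell marker, had 20, 860, 50 and 11 counts, and the replication helicase subunit Mcm4 had 11, 13, 6 and 140.

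Odorant and pheromone receptor genes held counts in all 4 libraries, and reads shared between receptor paralogs would leave tissue-restricted genes without such families far below them, but 72 genes of retina, skin, testis and other tissues had a median of 1.78 counts per kb against 1.93, a ratio of 0.92 (bootstrap interval 0.791 to 1.25, and 0.82 to 1.2 by library), which argues against paralogs as the main source. Genomic DNA of male cells was also excluded, since 4 single-copy Y genes had 1 count in total against 433 at the receptor density. A source counted evenly over all exons was argued against too, since the 197 receptor genes with a single exon block held 0.627 of the density of the 1282 others (bootstrap interval 0.489 to 0.79). Genomic DNA of female cells stays open. The ratio of 0.92 met the prediction set for it beforehand. The single-block value, a condition added after the data were seen, is not near what it predicts. How reads with several positions were counted, which could lower short single-block genes, is not given in the sources used here. The 9 receptor genes on the X had 0.668 of the autosomal density (0.485 to 0.852) but 1.17 of its median (0.869 to 1.46), and no biological explanation was tested.

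The deposited comparison called 404 genes where the F test called 0. The choice of test statistic accounts for this difference on the same genes and fit, where the quasi-likelihood F test called 0. That does not say which test is nearer the truth. Large counts in single libraries may feed the calls, since 61.4% of them had over 80% of their summed CPM in 1 library. The groups did not overlap in 63.9% of the calls and in 32.8% of all genes tested there. The calls were selected for a group difference in the same counts. On the 10808 genes of the main filter the likelihood ratio test on the quasi-likelihood fit called 272. In 20 tables of as many genes simulated without change, whose spread is understated, it called a median of 20.5 (8 to 35). The F test called a median of 0 and at most 2 in the same tables. The likelihood ratio test thus called more unchanged genes, while the F test found 10% of simulated log2 folds of 4 against 90%. The 3 splits of the 4 libraries into pairs are too few for a share under 0.05: 2 of them gave as many calls, with 404 for the real split and 502 for the highest other, endogenous 1 with overexpressed 3. An effect of miR-125a on some of these genes stays open.

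The erythroid, DNA replication and mitosis lists were lower by camera at the preset correlation, but not with an estimated correlation (adjusted p 0.978 for each) or by fry (0.966). By the edgeR test 0 members were called over all genes. With the estimated correlation only 0.2% of list tests simulated without change had a camera p under 0.05. Its high p thus does not exclude a lower list. More background in the overexpressing libraries would pull all expressed genes down, but the median log2 fold of the 2844 other genes above background was 0.13 (bootstrap interval 0.10 to 0.16), which argues against it. The lower erythroid pattern may come from 1 library alone, since without endogenous 3 the list's median was 0.72. For the cell cycle the highest median without 1 library was -0.35 for mitosis, over 19 members without endogenous 1. For DNA replication it was -0.07, over 12 members without endogenous 3. The tested members changed with the library, since the count filter was rerun. A single library and a group difference thus cannot be told apart with 2 libraries per group. An effect of miR-125a on proliferation stays among the open explanations, untested.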
